A study of Mus musculus with 8 samples.

How the data were processed

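Messenger RNA bound to tagged ribosomes was sequenced from embryonic mouse neurons. In bacTRAP mice, a tagged ribosomal protein is made under the control of a chosen gene, so that RNA on the ribosomes of 1 cell type can be pulled out of mixed tissue. The series' design text names a line driven by the dopamine transporter gene Slc6a3 and a line driven by the serotonin transporter gene Slc6a4. The libraries' own descriptions name the Slc6a3 line in all 8 cases, including the 2 serotonin libraries, so groups were taken from the titles, which the source labels match. Per the labels, embryos were dissected on embryonic day 15, and midbrain given as day 18 was dissected on day 15 and kept 3 days in vitro. This text is the same for all 8 libraries. Per the labels' protocols, cDNA was amplified by long-distance PCR, broken to about 200 bp, enriched with 10 cycles of PCR and sequenced as single reads of 100 bp.

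The values were raw read counts per gene, deposited as 1 table per library. Reads were aligned to mm10 with STAR, per the submitters' processing notes, and counted with featureCounts 1.4.3-p1 against a GENCODE annotation without regard to strand, per the file headers. Each table held 38924 genes with 1 count per gene. Counts of coding regions and of UTRs could therefore not be separated, and the comparison of these regions that the series title names was not analysed here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Near-identical genes such as Hba-a1 and Hba-a2, or Hbb-bs and Hbb-bt, are uncertain one by one. Gene symbols were attached by gene identifier to 37607 of the genes. Coordinates are those of the deposited tables.

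The libraries fell into 5 groups: dopamine datL (n = 2), dopamine datM (n = 2), dopamine Lateral (n = 1), dopamine Medial (n = 1) and serotonin (n = 2). The labels do not spell out the letters L and M. They also do not say whether replicates were separate animals, so p-values measure only the spread between these libraries, which may be technical. Per the file headers, the datL and datM libraries came from a run folder named for October, and the serotonin, Lateral and Medial libraries from lane 8 of another run. The headers of Lateral and Medial also carry the mark E18. Dopamine was therefore also compared with serotonin within lane 8. There the dopamine libraries carry the E18 mark and the serotonin libraries do not, so neuron type and this mark cannot be separated. The October run held dopamine libraries only, so within it no comparison with serotonin could be made.

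Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors, edgeR's default expression filter and Benjamini-Hochberg adjustment at a threshold of 0.05. Dopamine was compared with serotonin as 6 libraries against 2, and datL with datM in a fit of all 5 groups. Standard errors were derived from the log2 fold change and the test statistic. CPM is a count scaled to the library's total. The 28 gene lists, the tests and the alternatives not named below as added were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Their members were also adjusted over the list alone. Lateral and Medial, with 1 library each, were compared without a test: list medians were placed among 10000 random lists of the same size matched on mean expression. Folds against a group with 0 counts in every library were bounded with a floor of 3 counts over the group. Intervals are 95% intervals, Wilson for shares and exact Poisson for counts. Intervals and floors cover counting error only, since PCR copies carried no molecular identifiers.

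The genes named followed a fixed rule. Between dopamine and serotonin it took Slc6a3, Slc6a4, Th, Tph2 and Ddc, the 10 largest folds each way past the threshold with a mean of at least 5 CPM and no overlap, without unnamed gene models, and up to 4 members of each list by smallest p. Between datL and datM it took the 5 largest folds each way past the threshold, with the same minimum, and up to 4 members of the medial and the lateral dopamine list. Between Lateral and Medial it took the 5 largest ratios each way among genes with at least 100 counts whose datL minus datM difference had the same sign in both numbered pairs, where a gene at 0 in both libraries of a pair has no sign. Other genes are said to have been chosen after their values were seen.

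The alternatives were RLE factors, DESeq2 1.42.0, limma-voom, other expression filters, a replicate block, other sets of libraries, a test for folds above 2, and leaving out each library in turn. For lists they were camera with an estimated correlation, fry, the block and the same omissions. Voom with quality weights, list tests on subsets of the libraries, the counts of listed genes under each alternative, the values of Gad1 and Nes under them, and fold bounds without each library were added after seeing the data. Where an omission left a group with 1 library, that library was assumed to vary like the other groups. The fits were tested on simulated counts. At a dispersion of 0.05, the comparison of dopamine with serotonin, run on 13590 genes, recovered 100 of 100 genes changed by 2 log2 units and 100 of 100 changed by 4, with 9 false calls. That of datL with datM, run on 13701 genes, recovered 99 and 100, with 4 false calls. At the common dispersion of these libraries, given to every gene and adjusted over all genes, 1.96 for the first on 13567 genes and 1.43 for the second on 13744, both recovered 0 genes of either size, with 0 false calls.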

Results

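Ribosome-bound RNA from midbrain dopamine neurons was sequenced in 6 libraries, and from hindbrain serotonin neurons in 2. The dopamine libraries were 2 labelled datL, 2 labelled datM, 1 labelled Lateral and 1 labelled Medial. Total counts were 22695145 and 26212552 for datL, 27249827 and 24038427 for datM, 33216710 for Lateral, 22417739 for Medial, and 29470043 and 29157280 for serotonin. The 4 libraries of the October run detected 11708 to 12509 genes, and the 4 libraries of lane 8 detected 13703 to 15656. Scaled to the smallest total, the expected numbers were 11694 to 12353 and 13703 to 15340. The biological coefficient of variation was 1.47 within the datL pair and 1.46 within the datM pair, 0.63 within the serotonin pair and 1.02 for Lateral with Medial.

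The first comparison asked how ribosome-bound RNA differed between dopamine and serotonin neurons. Slc6a3, the dopamine transporter (ENSMUSG00000021609.6, chromosome 13, 73536747 to 73578672, mm10), stood at 239 ± 254 CPM (SD, n = 6) in dopamine libraries and 0.425 ± 0.359 CPM (SD, n = 2) in serotonin libraries. Th, the rate-limiting enzyme of dopamine synthesis (ENSMUSG00000000214.4, chromosome 7, 142892752 to 142931128), stood at 523 ± 337 CPM and 15.8 ± 7.31 CPM. Slc6a4, the serotonin transporter (ENSMUSG00000020838.6, chromosome 11, 76998603 to 77032340), stood at 1.53 ± 2.41 CPM and 1135 ± 85.5 CPM. Tph2, the enzyme that starts serotonin synthesis in neurons (ENSMUSG00000006764.8, chromosome 10, 115078641 to 115185022), stood at 9.72 ± 16.9 CPM and 2549 ± 510 CPM.

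Over all 13806 genes tested, edgeR placed 0 past the threshold. The smallest adjusted p was 0.108, and 648 genes had an unadjusted p under 0.05, where chance gives 690. DESeq2 called 133 genes and limma-voom 14. All 6 dopamine libraries lay above both serotonin libraries at 422 genes (3.06%) and below them at 1186 (8.59%), where chance gives 3.57% in each direction. That chance share takes all libraries as alike. Scaled to the smallest total, the datL and datM libraries were expected to detect 11694 to 12353 genes, and the serotonin libraries 14771 and 15134. The shares above and below therefore cannot be assigned to neuron type. Within lane 8, Lateral and Medial against serotonin gave 1849 genes of 13400 at an unadjusted p under 0.05, where chance gives 670. In edgeR 3 genes passed the threshold there. Aldh1a1 was higher in dopamine libraries, and Slc6a4 and Fev were lower. In edgeR, 23 listed genes passed when adjusted over the list alone, 14 higher and 9 lower in dopamine libraries, beside the 0 over all genes. Each of them but Aldh1l1 was higher, or lower, in 6 of 6 dopamine libraries than in both serotonin libraries. Within lane 8 each but Hbb-bt (edgeR adjusted p = 0.132) passed over its list in the same direction. The number was 14 without serotonin replicate 1 and 11 without serotonin replicate 2.

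Of 20 midbrain dopamine neuron genes, 6 rose when adjusted over the list alone. Aldh1a1, an enzyme of retinoic acid synthesis found in some dopamine neurons, stood at 430 ± 346 CPM in dopamine and 0.460 ± 0.165 CPM in serotonin libraries (log2 fold change 9.91, SE 1.47, edgeR adjusted p = 0.00047). Slc6a3 had a log2 fold change of 9.23 (SE 1.53, edgeR adjusted p = 0.000663) and Th of 5.16 (SE 0.96, edgeR adjusted p = 0.00126). The others were Nr4a2, Lmx1a and Foxa1, transcription factors of developing dopamine neurons, with log2 fold changes of 4.94, 5.74 and 2.72. Within the list of midbrain transcription factors, Lmx1a (edgeR adjusted p = 0.0045) and Pou4f1 (log2 fold change 3.69, edgeR adjusted p = 0.0252) passed and Foxa1 did not (edgeR adjusted p = 0.054). Neither Lmx1a nor Pou4f1 passed in that list without serotonin replicate 1 (adjusted p = 0.0874 for each) or replicate 2 (adjusted p = 0.0567 for Lmx1a and adjusted p = 0.335 for Pou4f1), nor Pou4f1 without datM replicate 1 (adjusted p = 0.053). Over all alternatives the adjusted p ran from 1.25e-10 to 0.273 for Lmx1a and from 3.33e-05 to 0.335 for Pou4f1. In limma-voom, Slc6a3, Th, Aldh1a1 and Nr4a2 did not pass over their list (adjusted p = 0.206), while over all alternatives the adjusted p of Slc6a3 ran from 1.19e-21 to that value.

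Of 12 serotonin neuron genes, 3 fell when adjusted over the list alone. Fev, a transcription factor of serotonin neurons, stood at 0.0671 ± 0.125 CPM in dopamine and 136 ± 8.33 CPM in serotonin libraries (log2 fold change -10.89, SE 1.58, edgeR adjusted p = 0.000239). Slc6a4 had a log2 fold change of -9.50 (SE 1.80, edgeR adjusted p = 0.00132) and Tph2 of -8.07 (SE 2.11, edgeR adjusted p = 0.0102). These 3 calls held without each library in turn. Slc6a4 and Fev had 0 counts in the 4 datL and datM libraries. In Lateral and Medial, Slc6a4 stood at 5.27 and 3.93 CPM.

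Of 14 genes for synthesis, storage and breakdown of monoamines, which both neuron types use, 2 fell when adjusted over the list alone and 13 had negative log2 fold changes. Gchfr, a regulator of biopterin cofactor synthesis, had a mean of 1774 ± 116 CPM in serotonin libraries and a log2 fold change of -7.11 (SE 1.81, edgeR adjusted p = 0.0199). Ddc, the decarboxylase of both pathways, stood at 191 ± 84.5 CPM in dopamine and 763 ± 153 CPM in serotonin libraries (log2 fold change -1.88, SE 0.50, edgeR adjusted p = 0.0199). Neither passed without serotonin replicate 1 (edgeR adjusted p = 0.0648 for Gchfr and adjusted p = 0.198 for Ddc) or without serotonin replicate 2 (adjusted p = 0.0518 for both). Over all alternatives the adjusted p ran from 0.000376 to 0.0762 for Gchfr and from 0.000376 to 0.198 for Ddc.

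**Figure D1:**
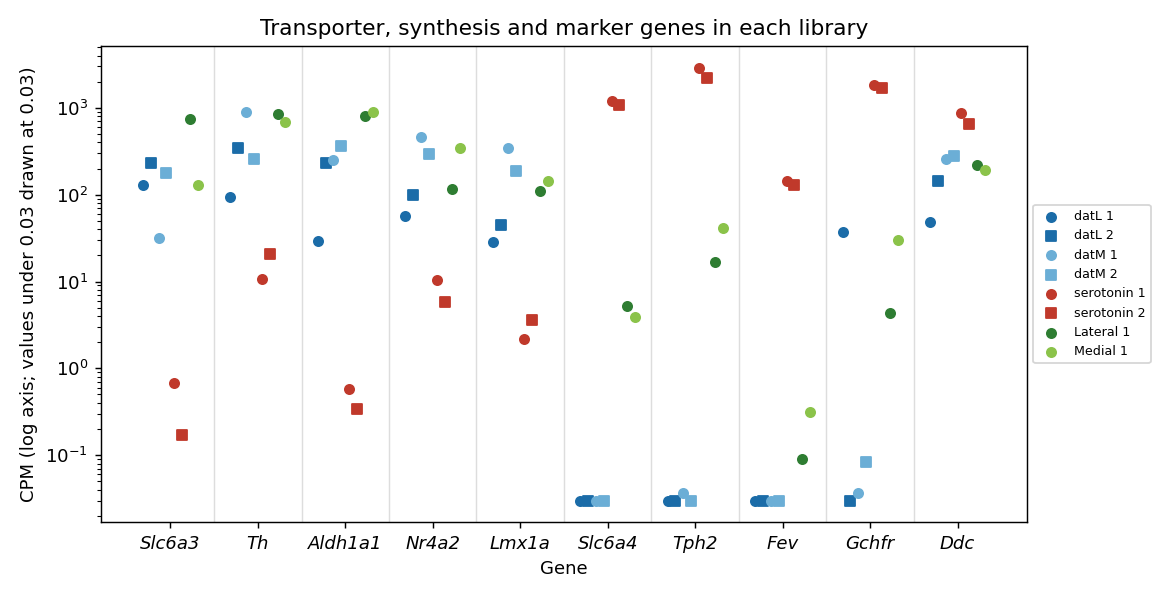
CPM on a log axis for 10 genes, with 1 point for each of the 8 libraries; circles are replicate 1, squares replicate 2, and values under 0.03 CPM are drawn at 0.03. Slc6a3, Th, Aldh1a1, Nr4a2 and Lmx1a lie higher in the 6 dopamine libraries, and Slc6a4, Tph2, Fev, Gchfr and Ddc in the 2 serotonin libraries.

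Genes of other hindbrain neurons were low in all libraries but were counted in serotonin libraries. Dbh and Phox2a, of noradrenaline neurons, had 0 counts in the 6 dopamine libraries, at least 61.0-fold and 48.0-fold lower than the 1.18 ± 0.498 and 0.923 ± 0.586 CPM of serotonin libraries (edgeR adjusted p = 0.00404 for each over the list alone, from 0.00191 to 0.0968, the value in DESeq2, over the alternatives). Hoxa2, a patterning gene of the hindbrain, was at least 169-fold lower (edgeR adjusted p = 0.0063 over the list alone, from 0.000288 to 0.067, the value with no expression filter, over the alternatives). Without serotonin replicate 2 the bounds were 26.4-fold for Phox2a and 82.8-fold for Hoxa2, and without serotonin replicate 1 that of Hoxa2 was 255-fold. All these bounds cover counting error only and not the spread between libraries. Slc18a2, for example, had 0 counts in datL replicate 1 and 3982 in datM replicate 2. The bounds are therefore not lower limits on the fold between the neuron types. Of 16 neuropeptide genes, 1 passed over the list alone: Scg2, a secretory granule protein, stood at 212 ± 81.7 CPM in dopamine and 852 ± 50.4 CPM in serotonin libraries (edgeR adjusted p = 0.00605). It did not pass without serotonin replicate 1 (adjusted p = 0.0578) or replicate 2 (adjusted p = 0.0849), and its adjusted p ran from 2.96e-05 to 0.0944 over all alternatives.

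Some listed genes of glia and blood passed as well. Of 11 astrocyte genes, 3 rose when adjusted over the list alone, and all 11 had positive log2 fold changes. Sox9 stood at 158 ± 72.7 CPM in dopamine and 28.2 ± 1.98 CPM in serotonin libraries (edgeR adjusted p = 0.0116), Fabp7 at 1773 ± 700 and 490 ± 55.5 CPM (edgeR adjusted p = 0.0116) and Aldh1l1 at 367 ± 209 and 78.9 ± 46.6 CPM (edgeR adjusted p = 0.0417). Sox9 and Fabp7 are also made in radial glia, the progenitors of the embryonic brain. Of 8 red blood cell genes, 4 globins rose over the list alone, with Hba-a1 at 85.3 ± 46.1 and 8.96 ± 0.767 CPM (edgeR adjusted p = 0.0181). None of these 7 calls held without serotonin replicate 1 (adjusted p of 0.144 to 0.333) or without serotonin replicate 2 (0.0991 to 0.139). Aldh1l1 also did not pass without datM replicate 1 (adjusted p = 0.0785), datM replicate 2 (adjusted p = 0.0611), Lateral (adjusted p = 0.0794) or Medial (adjusted p = 0.0635), nor with the replicate block (adjusted p = 0.0638), and its adjusted p ran from 0.00142 to 0.333 over all alternatives. Nor did Hba-a2 pass without datM replicate 1 (adjusted p = 0.051) or Hbb-bt without datL replicate 1 (adjusted p = 0.0531) or datM replicate 1 (adjusted p = 0.0554). The globins did not pass in limma-voom (adjusted p = 0.268) or with 5 groups (0.0711 to 0.0731), and over all alternatives the adjusted p of Hba-a1 ran from 1.23e-05 to 0.268. All 16 progenitor and proliferation genes had positive log2 fold changes. In edgeR 0 of them passed over the list alone, and 3 had an unadjusted p under 0.05.

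By camera, 10 of 27 testable lists passed. Higher in dopamine libraries were midbrain dopamine genes (median log2 fold change 3.90, adjusted p = 8.8e-10), midbrain transcription factors (2.15, adjusted p = 3.16e-06), red blood cell genes (3.42, adjusted p = 5.2e-06), progenitor genes (2.72, adjusted p = 1.54e-05), astrocyte genes (2.46, adjusted p = 1.87e-05) and axon guidance genes (1.15, adjusted p = 0.0399). Lower were serotonin neuron genes (-2.39, adjusted p = 2.02e-07), monoamine genes (-1.35, adjusted p = 0.00033), noradrenaline genes (-4.44, adjusted p = 0.00033) and cholinergic and motor neuron genes (-3.41, adjusted p = 0.00212). With an estimated correlation, midbrain transcription factors and progenitor genes passed (adjusted p = 0.0459 for each). The other 8 did not: adjusted p = 0.0973 for dopamine, serotonin and cholinergic genes, adjusted p = 0.0654 for noradrenaline, adjusted p = 0.0979 for astrocyte, adjusted p = 0.108 for monoamine, adjusted p = 0.111 for red blood cell and adjusted p = 0.439 for axon guidance genes. Without serotonin replicate 2 the cholinergic list did not pass (adjusted p = 0.0676, over all alternatives from 0.00106 to 0.0973). The axon guidance list did not pass without datL replicate 2, datM replicate 2, Lateral, Medial or either serotonin library (0.0516 to 0.104, over all alternatives from 0.0121 to 0.869). By fry, which asks whether a list's genes move one way on balance, the dopamine (adjusted p = 0.0759), astrocyte (adjusted p = 0.154), red blood cell (adjusted p = 0.138) and axon guidance lists (adjusted p = 0.869) did not pass either.

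The other 17 lists gave adjusted camera p from 0.0798 to 0.979, and for neuropeptide, immediate early and ribosomal protein genes the median and the camera direction differed in sign. Only 2 Hox genes were abundant enough to test, too few for camera. Within lane 8, camera gave adjusted p = 7.85e-07 for astrocyte genes, adjusted p = 1.24e-05 for progenitor genes and adjusted p = 0.205 for red blood cell genes. Oligodendrocyte (adjusted p = 0.000788), endothelial (adjusted p = 0.0126) and medial ventral tegmental dopamine genes (adjusted p = 0.00504) were also higher in dopamine libraries there, and did not pass over all libraries (adjusted p = 0.286, adjusted p = 0.0955 and adjusted p = 0.117). Camera gave adjusted p = 7.85e-07 for dopamine and adjusted p = 5.84e-05 for serotonin genes. Ribosomal protein genes were lower in dopamine libraries there (median log2 fold change -0.65, adjusted p = 7.85e-07) and did not pass over all libraries (-0.02, adjusted p = 0.532).

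**Figure D2:**
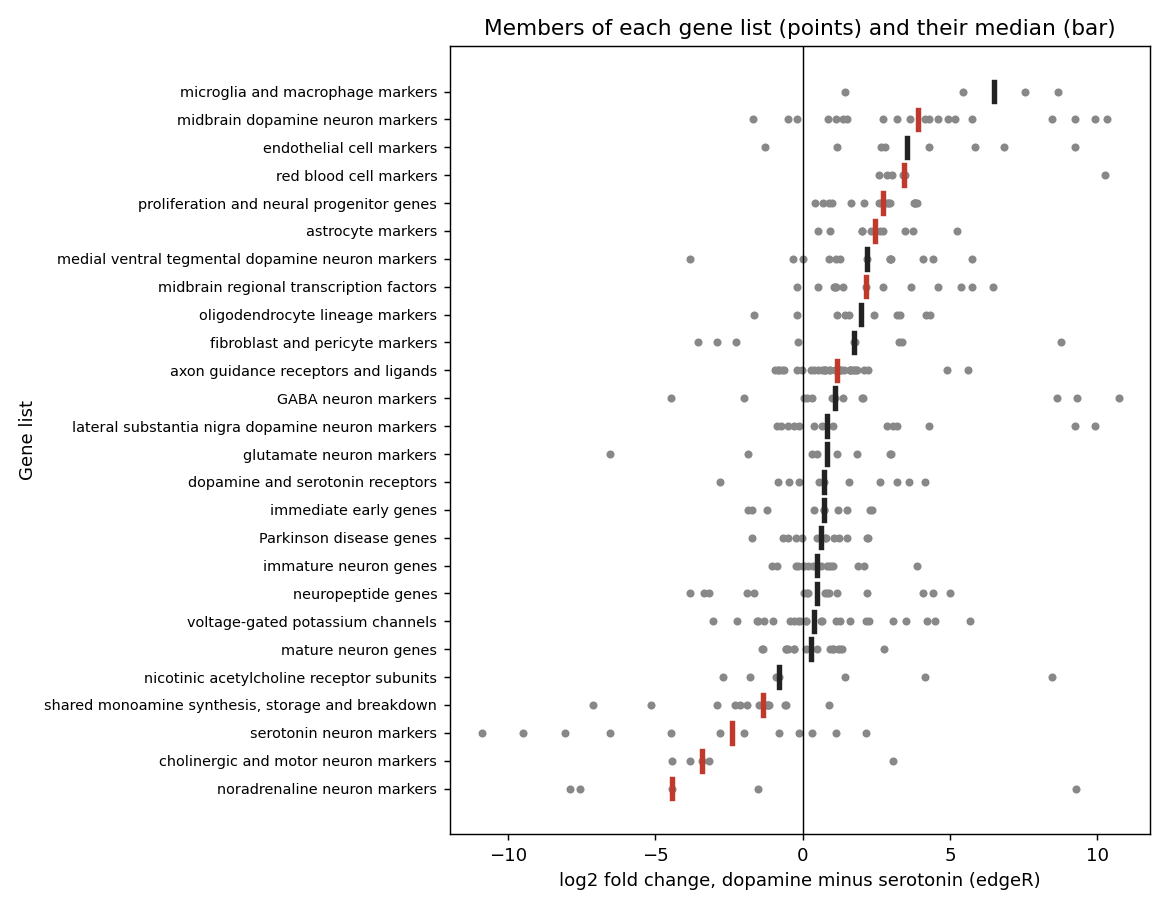
Log2 fold change, dopamine minus serotonin, of the tested members of each gene list, without the Hox and ribosomal protein lists; points are genes, bars are medians, and red bars mark lists past an adjusted camera p of 0.05 with the preset correlation. The median of midbrain dopamine genes lies at 3.90 and that of serotonin neuron genes at -2.39.

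The second comparison set datL against datM dopamine libraries. Over log2 CPM of 13806 genes, Pearson's r was 0.646 within the datL pair and 0.642 within the datM pair. Between datL and datM libraries it was 0.599 to 0.663, so libraries of the same group were no more alike than libraries of different groups. Gad1, an enzyme that makes the inhibitory transmitter GABA, stood at 231 ± 180 CPM (SD, n = 2) in datL and 0.875 ± 0.943 CPM (SD, n = 2) in datM. Anxa1, a marker of some nigral dopamine neurons and a member of the lateral list, stood at 0.0602 ± 0.0228 CPM and 142 ± 37.3 CPM. Nes, an intermediate filament gene of neural progenitors, stood at 23.1 ± 4.24 CPM and 292 ± 32.8 CPM. Anxa1 also stood at 59.9 and 45.6 CPM in the serotonin libraries, so here it was not particular to dopamine neurons. Gad1 had 20743 counts in Lateral, 5374 in Medial, and 2270 and 3152 in the serotonin libraries. Its counts were 2354 and 9394 in datL and 42 and 5 in datM, so it was low in datM rather than particular to datL. Gad1 and Nes were chosen after their values were seen.

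These 3 genes were the listed genes past the threshold in edgeR adjusted over the list alone: Gad1 rose in datL (log2 fold change 8.09, SE 1.28, adjusted p = 0.00459), and Anxa1 (-11.01, SE 1.28, adjusted p = 0.000718) and Nes (-3.58, SE 0.71, adjusted p = 0.0225) fell. Anxa1 passed under each alternative run. Nes did not pass without datL replicate 1 (adjusted p = 0.0566), serotonin replicate 1 (adjusted p = 0.05001) or serotonin replicate 2 (adjusted p = 0.0509), and its adjusted p ran from 6.01e-07 to 0.105 over all alternatives. Gad1 did not pass where Lateral was joined to datL and Medial to datM without a block (adjusted p = 0.292, the highest of its alternatives, from 3.89e-14). Over all 15177 genes, edgeR placed 0 past the threshold, with 1050 at an unadjusted p under 0.05, where chance gives 759. The smallest adjusted p was 0.597, while DESeq2 called 1609 genes and limma-voom 243. Without either serotonin library edgeR called 6. The count of listed genes was 8 without datL replicate 1, 51 without datL replicate 2, 5 without either datM library and 10 without either serotonin library.

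In the medial list, Lmx1a stood at 36.7 ± 11.9 CPM in datL and 264 ± 111 CPM in datM (edgeR adjusted p = 0.0795 over the list alone). In the lateral list, Sncg stood at 123 ± 81.1 CPM and 5.57 ± 7.70 CPM (edgeR adjusted p = 0.261 over the list alone). Of 28 lists, 3 passed by camera. GABA neuron genes were higher in datL, with 12 of 13 positive (median log2 fold change 5.39, or 3.42 with genes at 0 in datM placed at their bound, adjusted p = 4.27e-05). Ribosomal protein genes were higher (0.70, adjusted p = 0.00172), and midbrain dopamine genes were lower, with 16 of 20 negative (-1.77, adjusted p = 0.00196). With an estimated correlation 0 lists passed, at adjusted p = 0.410 for GABA, adjusted p = 0.937 for ribosomal protein and adjusted p = 0.433 for dopamine genes, the highest of their alternatives. By fry the dopamine (adjusted p = 0.068) and ribosomal protein lists (adjusted p = 0.867) did not pass, and the GABA list did (adjusted p = 0.00349). The other 25 lists gave adjusted camera p from 0.114 to 0.997. Among them, fry passed the astrocyte list (median log2 fold change -1.195, adjusted p = 0.00349). Fry also passed the neuropeptide list, higher in datL, and the lateral dopamine list, lower in datL and so opposite to camera's direction (adjusted p = 0.0481 for each). Ribosomal protein genes made up 7.79% of counts in datL replicate 1 and 2.60% to 4.79% in the other libraries. Without that library their direction turned (adjusted p = 0.20) and the dopamine list did not pass (adjusted p = 0.0856). Without datM replicate 1 the dopamine list did not pass (adjusted p = 0.0671), nor the ribosomal list without datM replicate 2 (adjusted p = 0.492).

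**Figure D3:**
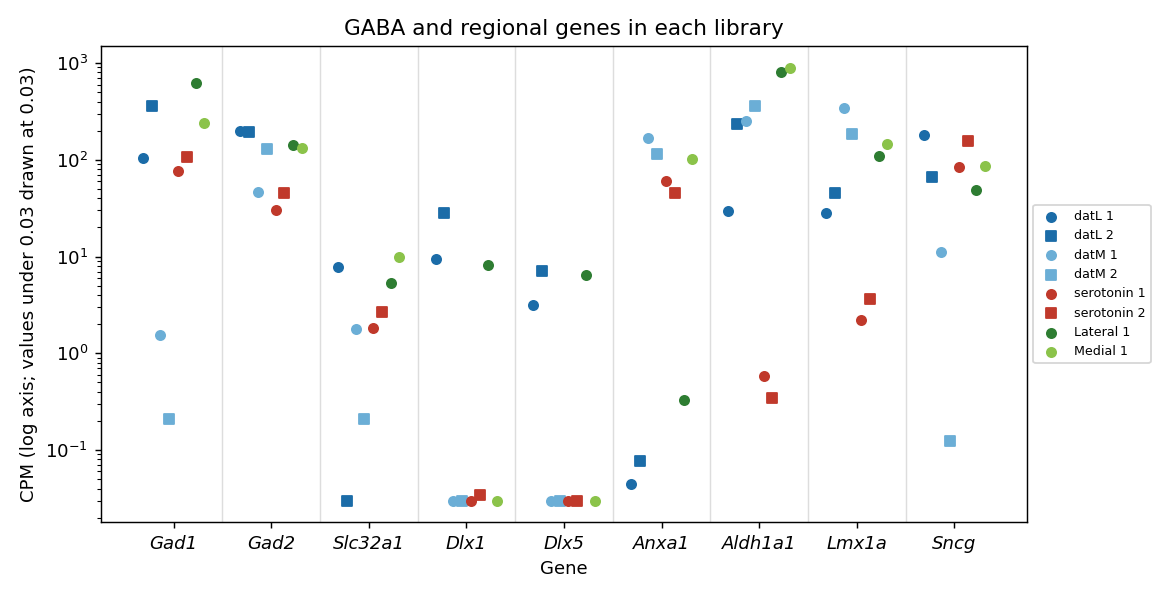
CPM on a log axis for 9 GABA and regional genes, with 1 point for each of the 8 libraries; circles are replicate 1, squares replicate 2, and values under 0.03 CPM are drawn at 0.03. Anxa1 lies at 0.0441 and 0.0763 CPM in datL and 0.331 CPM in Lateral, and at 168 and 115 CPM in datM and 102 CPM in Medial. In the serotonin libraries it lies at 59.9 and 45.6 CPM.

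The third comparison set the Lateral library against the Medial library, with no replicates. Meis2, a transcription factor gene, stood at 63.6 CPM in Lateral and 0.134 CPM in Medial. Lateral was also far higher for Bloc1s5, Tbce, Adk and Haus1, at 23.4 to 43.4 CPM against at most 0.0446 CPM. Spef2, Cyba, Ak7 and 1700028P14Rik had 0 counts in Lateral and 21.9 to 36.2 CPM in Medial, and Efcab2 stood at 0.0903 and 65.6 CPM. The mean datL minus datM difference had the same sign as this one for Adk, Meis2 and the 5 genes higher in Medial, and the opposite sign for Bloc1s5, Tbce and Haus1. Among all 5489 genes that met the rule before ranking, 2744 had the sign of Lateral minus Medial.

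Among 11867 genes with at least 100 counts, 3012 differed by more than 4-fold, 1994 higher in Lateral and 1018 in Medial. The serotonin pair, compared in the same way, differed by more than 4-fold at 836 of 11631 genes. Lateral nigral dopamine genes had a median log2 ratio of 2.68, at percentile 99.5 of matched random lists. Midbrain transcription factors lay at -0.96 (percentile 0.93), glutamate neuron genes at -1.61 (percentile 0.16), fibroblast and pericyte genes at -1.33 (percentile 0.12), endothelial genes at -1.01 (percentile 0.98), serotonin neuron genes at -0.87 (percentile 1.29) and ribosomal protein genes at -0.60 (percentile 0). Medial ventral tegmental dopamine genes lay at -0.23 (percentile 18.3).

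The last comparison asked whether the letters L and M order genes as the words Lateral and Medial do. Across 15177 genes, which are not independent replicates, the datL minus datM and Lateral minus Medial differences had Pearson's r = 0.042 and Spearman's rho = 0.018. The numbered pairs gave Pearson's r of 0.024 and 0.037 with Lateral minus Medial, and 0.068 with each other. The other ways to divide the 4 libraries gave -0.032 and -0.009. Of 1954 genes differing by more than 4-fold in both, 52.7% had the same sign.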

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

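The tests of carry-over and of serotonin neuron RNA, and the divisions without marker lists, were chosen after the result was seen. Among 103 series of values over the 6 dopamine libraries, 18 had 1 library whose gap to the nearest other, divided by the whole range, was large, where chance gives about 5.2. In datL replicate 1 the ribosomal protein share was high (ratio 0.693). That library was lowest for Ddc (0.639), Aldh1a1 (0.644), Pdgfra (0.692), Mcm3 (0.743), Robo2 (0.756) and Gigyf2 (0.665), with Aldh1a1 at 29.4 CPM against 232 to 898 CPM in the other dopamine libraries. Lateral was highest for Calca (0.854) and Col1a2 (0.723), and among the dopamine libraries it alone had counts of Chrna5, Htr5b and Kcnd1 (ratio 1 for each). Medial alone had counts of Slc17a8 (ratio 1), and it was lowest for Sox6 (0.827), at 0.0892 CPM against 27.0 to 73.1 CPM. Aif1 was highest in datM replicate 1 (0.681), Cartpt lowest in datL replicate 2 (0.673) and Nts lowest in datM replicate 2 (0.653).

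The 10 gene lists past the threshold between dopamine and serotonin were set against all 28 divisions of the libraries into 6 and 2. The real division alone gave as many (1 of 28) and the highest other gave 8, among divisions that ignore the lane. Some of these lists mark the neuron types that define the groups, and the serotonin pair varied least. The share therefore does not exclude chance. Of the 6 divisions that set 2 libraries of lane 8 apart, the others gave 2 to 8, and 6 divisions are too few for a share under 0.05. Without the lists that mark either neuron type or its region, the real division alone gave 6 (1 of 28) and the highest other 5, a difference of 1 list. The division with 8 sets Lateral and Medial, which share a lane and the E18 mark, against the rest. In edgeR's gene test the real division gave 0 genes (648 at an unadjusted p under 0.05, and 133 by DESeq2 and 14 by limma-voom). Setting datL replicate 2 and datM replicate 2 apart gave 10, and setting both datM libraries apart gave 5. Setting datL replicate 1 and datM replicate 1 apart gave 0, as did setting both datL libraries apart. A structure among the dopamine libraries was described but not tested. On the first principal component of log2 CPM (25.6% of the variance), the datL and datM libraries lay at -215 to -35.1. The serotonin, Lateral and Medial libraries lay at 97.8 to 133, so this axis divided the runs and not the neuron types. Lateral had Pearson's r of 0.841 and 0.835 with the serotonin libraries and 0.758 with Medial.

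Lateral and Medial held serotonin neuron transcripts, with Tph2 at 0.659% and 1.63% and Slc6a4 at 0.464% and 0.346% of their mean levels in serotonin libraries. Carry-over of reads from serotonin libraries on the same lane would keep the proportions of those libraries, and the Tph2 counts then predict 741.9 counts of Slc6a4 and Fev. The 273 counted (95% interval 242 to 307, counting error only) argue against carry-over in those proportions as the whole source. RNA of serotonin neurons with the same proportions would miss the prediction too, so these counts do not favour it over carry-over. RNA of serotonin neurons in the dissected midbrain stays open, since the lowest count of the 3 genes, of Fev in Lateral, was 3, which is no higher than the floor, and the pull-down through Slc6a3 is meant to remove such RNA. The datL and datM libraries were not on that lane, so their low counts, 1 of Tph2 and 0 of Slc6a4 and Fev, cannot be assigned to lane or group.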

How the results depend on the processing

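Counts of listed genes, quality weights and lists on subsets of libraries were chosen after seeing the data. Between dopamine and serotonin, genes past the threshold numbered 0 in edgeR, 133 with DESeq2, 14 with limma-voom, 351 with quality weights, 3 at 5 CPM or more, 2 with 5 groups, 2 for datL and datM alone, 3 for Lateral and Medial alone and 0 to 1 without 1 library. Listed genes numbered 23, but 51 with DESeq2, 36 for datL and datM alone, 57 for Lateral and Medial alone, 59 with quality weights and 11 to 29 without 1 library. Between datL and datM, genes numbered 0, but 1609 with DESeq2, 243 with limma-voom and 0 to 6 without 1 library. Listed genes numbered 3, but 53 with DESeq2, 14 with limma-voom, 10 with no filter, 11 at 5 CPM or more, 6 with the 4 libraries alone, 5 with L taken for Lateral and title style as a block, 6 without that block and 5 to 51 without 1 library. Lists went from 10 to 2 with an estimated correlation and 6 with fry, and between datL and datM from 3 to 0 with an estimated correlation and 1 to 3 without 1 library. Genes over 4-fold apart between Lateral and Medial numbered 1400 at a higher count minimum, where fewer genes qualify. Elsewhere the cause was not tested.

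Direction turned for fibroblast genes without serotonin replicate 1 (adjusted p = 9.123e-05, omissions up to 0.7687), while without serotonin replicate 2 they passed in the first direction (adjusted p = 0.008497), ribosomal protein genes between dopamine and serotonin within lane 8 (adjusted p = 7.849e-07) and without datL replicate 1 (adjusted p = 0.02288, omissions up to 0.9097), ribosomal protein genes between datL and datM without datL replicate 1 (0.1996, omissions from 2.598e-14 to 0.492), and lateral dopamine genes by fry (adjusted p = 0.04808). The cause was not tested. Of 2834 values of single genes and lists under alternatives, 2514 kept their direction and side of the threshold, 101 fell short of it, 139 newly passed, 5 turned and 75 changed sign with neither value past it. DESeq2 gave no p for 18 named values.

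The labels give same-numbered libraries only a number in common. Their deviations correlated at 0.101 for datL and datM, 0.015 for datL and serotonin and -0.004 for datM and serotonin, and a shared origin of same-numbered datL and datM libraries stays open. With the replicate block, genes numbered 0 in both comparisons, listed genes 26 and 8, and lists 10 and 3. Of the named genes' calls, the block ended that of Aldh1l1 (adjusted p = 0.06375) and no other. In simulated counts with 1 dispersion for all genes, adjusted over all genes, the same numbers of libraries recovered changed genes at low dispersion and 0 at the observed common dispersion.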

Other observations

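The tests of the run, of the share of targeted neurons and of globin shares were chosen after the result was seen. Some unlisted genes also separated the libraries, though 0 genes passed in edgeR over all genes (648 at an unadjusted p under 0.05, 133 past the threshold in DESeq2 and 14 in limma-voom). They were chosen after their values were seen. Slc7a11, a cystine transporter, stood at 304 ± 173 CPM (SD, n = 6) in dopamine and 3.00 ± 0.795 CPM (SD, n = 2) in serotonin libraries, higher in 6 of 6 (log2 fold change 6.82, edgeR adjusted p = 0.108; within lane 8 6.33, adjusted p = 0.128). Chgb, a secretory granule protein, stood at 62.5 ± 45.9 and 740 ± 89.6 CPM, lower in 6 of 6 (log2 fold change -3.45, edgeR adjusted p = 0.327; within lane 8 -3.44, adjusted p = 0.261). Malat1, a noncoding RNA, stood at 1450 ± 1040 and 111 ± 30.2 CPM (log2 fold change 3.85, edgeR adjusted p = 0.3275). Meg3, another noncoding RNA, stood at 760 ± 487 and 126 ± 28.4 CPM (log2 fold change 2.68, edgeR adjusted p = 0.3275). Both were higher in 6 of 6, while Lars2 was lower in 6 of 6 (log2 fold change -2.33, edgeR adjusted p = 0.8846). The cause was not tested. Among GABA genes, Dlx1 and Dlx5, forebrain transcription factors, were counted in both datL libraries (9.34 and 28.4 CPM for Dlx1, 3.13 and 7.10 CPM for Dlx5) and in Lateral (8.13 and 6.44 CPM), and had 0 counts in both datM libraries and Medial. Neither passed between datL and datM over the list alone (edgeR adjusted p = 0.0585 for Dlx1 and adjusted p = 0.12 for Dlx5).

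By camera with the preset correlation, astrocyte, progenitor and red blood cell lists were higher in dopamine libraries. With an estimated correlation this held for the progenitor list (adjusted p = 0.0459) and not for the astrocyte (adjusted p = 0.0979) or red blood cell list (adjusted p = 0.111). Within lane 8 the astrocyte list (adjusted camera p of 7.849e-07) and the progenitor list (1.241e-05) were also higher. Lateral and Medial, the dopamine libraries there, carry the E18 mark and the serotonin libraries do not. A difference in stage could thus raise these lists in lane 8. The values there therefore cannot decide on the October run. For the red blood cell list the run also stays open (0.2046): its median was 2.17 there, but members went both ways. Over the list alone Hba-a1, Hba-a2, Hbb-bs and Alas2 were higher, and Hbb-y and Hba-x were lower. These 2 embryonic globins had 0 counts in Lateral and Medial, so the list's p mixes them with its other genes. A lower share of the targeted neurons would raise markers of the other cell types alike, and a permutation of genes among the non-neuronal lists gave p = 0.0177 over all 50 genes and p = 0.159 over the 34 genes with a mean of at least 5 CPM, a minimum set after the first value was seen; within lane 8 oligodendrocyte (0.000788) and endothelial lists (0.0126) were higher as well, and fibroblast genes did not pass (0.247), so a lower share stays open, as does the untested difference between midbrain and hindbrain tissue.

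Embryonic globins (Hbb-y, Hba-x and Hbb-bh1) made up 12.1% to 24.2% of globin counts in the 6 libraries without the E18 mark, with 95% Wilson intervals of 11.2% to 13.0% for the lowest and 22.1% to 26.4% for the highest. Lateral and Medial had 0 of 3278 and 0 of 5286 globin counts, which allows shares of up to 0.0915% and 0.0568% at a floor of 3 counts (upper Wilson bounds 0.117% and 0.0726%). The serotonin libraries, on the same lane, had lower bounds of at least 14.9%, which argues against the lane. As a hypothesis, Lateral and Medial may be of a later stage than the other libraries, which goes with the E18 mark. Age and the 3 days in vitro cannot be separated by these values.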
